A study of Oryza sativa Japonica Group with 64 samples.

How the data were processed

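RNA sequencing of flag leaves and anthers of rice was deposited as 2 tables of raw read counts per gene, 1 per tissue, which the authors made from their reads. Values were whole counts for 55986 genes in each table, with rice locus identifiers, 89 of them for sequences of no chromosome. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. Coordinates are therefore not given. Each library column was matched to its sample by its label, and all 64 libraries were used. Total counts lay between 18.05 M and 25.96 M reads in anthers and between 12.91 M and 20.45 M in leaves, so that 10 counts were worth 0.385 to 0.554 CPM in anthers and 0.489 to 0.774 CPM in leaves. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

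Libraries were grouped per the labels by tissue, genotype, photoperiod and collection time, with 2 biological replicates per group. Whether replicate numbers pair libraries was checked by correlating the replicate differences of pairs of groups across genes. In anthers r lay between −0.311 and 0.332 over 28 pairs of groups, with 7 above 0.1 and 7 below −0.1, and in leaves between −0.258 and 0.231 over 276 pairs, with 30 above and 19 below. The numbers therefore did not pair the libraries and were not used as a block. Replicates were not duplicates of each other, since the chi-square per gene between them was at least 8.409 in anthers and 6.626 in leaves.

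Each tissue was fitted by itself in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 25203 of 38063 genes with any count in anthers and 22095 of 38890 in leaves. Library sizes were scaled by TMM, with factors from 0.93 to 1.05 in anthers and from 0.63 to 1.41 in leaves. Negative binomial dispersions were trended, and a quasi-likelihood F-test was applied to contrasts of the group means, averaged over collection times. The contrasts were csa against WT in SD and in LD, SD against LD in WT and in csa, and the difference of the genotype contrasts between SD and LD (genotype by photoperiod). In anthers csa was also compared with WT in SD at 16:00 and at 04:00. For the leaf time course, each genotype and photoperiod was given a cosine and a sine term with a period of 24 h. A gene was called rhythmic when both terms of its group differed from 0 together, and its pattern was called different when both terms differed between groups together. The p-values were adjusted by Benjamini-Hochberg over all tested genes within each contrast, at a threshold of 0.05. CPM are given on TMM-scaled totals, means with SD over libraries, and fold changes with their standard error (SE). A fold against a group with 0 counts is given as a bound against a floor of 3 counts over the group.

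There were 10 gene lists with 125 genes, of which 124 were in the tables; the symbols and locus identifiers were written from memory. They cover the circadian clock, flowering and photoreceptors, CSA and its paralog, sugar transport and invertase, starch and sucrose metabolism, tapetum and pollen wall, late pollen, photosynthesis (as leaf markers), jasmonate and heat shock. The reference assembly at hand held none of the tables' identifiers. Of the list symbols 75 were found in it on the chromosome of the identifier, 1 only on another chromosome and 49 not at all, so that the identity of the last 49 rests on memory alone. Lists chosen by words in gene descriptions were left out, because the reference held no descriptions. List tests used camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over all lists and contrasts of a tissue, and were repeated with a correlation estimated from the data and with fry. Counts of list genes were also adjusted over the list alone.

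Named genes follow a rule. CSA came first, then the members of the lists that passed the threshold, up to 12 per comparison with the lowest p. To these were added genes with the largest fold among those with a mean of at least 5 CPM in the higher group, the same sign at each time and no overlap between the groups at any time. For the genotype by photoperiod contrast the mean was that of the highest group, and overlap was not checked. Since the reference gave no descriptions, genes of this last kind were limited to up to 2 rises and 2 falls per comparison and are named by their identifier. Other list genes and the leaf marker genes were chosen after their values were seen.

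Alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no filter on low counts, a minimum fold of 2, only the compared libraries, collection time as a factor in leaves, the replicate number as a block, and each library left out in turn. Fits without a library kept the tested genes and the trended dispersions and estimated the TMM factors and the quasi-likelihood dispersions again; the lone library of a group was assumed to vary like the others. Leaves without the 12:00 collections were added after the data were seen. The tests of a linked segment on chromosome 1 and of younger csa anthers in SD were changed after their first results were seen. In other splits of the compared libraries, collection time was a factor beside the group, or a cosine and a sine term for diel patterns. Their gene counts therefore differ from those of the contrasts. The splits were not balanced over collection times. The gene lists, the comparisons, the naming rule and the other alternatives were fixed before the data were examined.

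The anther and leaf models were tested on simulated data with the measured means and the trended dispersions, without the extra spread of single genes. Changes were planted only in genes with a mean of at least 5 CPM. In the rhythm test all other genes were flat. Recovery and false calls may therefore look better than in the data. Of 100 genes given a 2-fold change between csa and WT in SD, 91 were called in anthers and 100 in leaves, with 8 false calls of 24597 and 5 of 21887 genes. Of 100 leaf genes given a rhythm of 2 on the log2 scale from peak to trough 97 were called, and at 1 on that scale 17 were called. Of 100 genes given a different pattern at these sizes 69 and 1 were called, so that weak differences in rhythm were out of reach.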

Results

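RNA from rice (Oryza sativa ssp. japonica) was sequenced to compare wild type (WT) with the csa mutant under short days (SD) and long days (LD). CSA (carbon starved anther) encodes a MYB transcription factor needed for sugar supply to the anther, and csa plants are known to be male sterile in SD and fertile in LD. Plants grew in a paddy field at a natural day length of 14.5 h (LD), and SD plots were covered from 18:00 to 6:00, which left 12 h of light. Flag leaves were taken every 4 h from 08:00 on, at 6 times over 24 h, at anther stage 12. Anthers came from the same tillers at 16:00 and 04:00. Each combination of tissue, genotype, photoperiod and time had 2 biological replicates. This gave 48 leaf libraries (12 per genotype and photoperiod) and 16 anther libraries (4 per genotype and photoperiod). Total counts per library lay between 18.05 M and 25.96 M reads in anthers (median 21.08 M) and between 12.91 M and 20.45 M in leaves (median 15.37 M). In anthers 25203 genes were tested, and in leaves 22095. Replicate pairs correlated across genes with Pearson r of log2 CPM (counts scaled to the library total) between 0.9664 and 0.9887 in anthers and between 0.9712 and 0.9859 in leaves; genes are not independent replicates. The first principal component held 48.9% of the variance in anthers and 40.1% in leaves.

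The transcript of the mutated gene itself, CSA (LOC_Os01g16810), was measured first in every library. In anthers it was abundant in both genotypes. In SD, WT libraries had 107, 85.2, 92.9 and 123 CPM and csa libraries 87.6, 123, 135 and 133 CPM. In LD, WT libraries had 74.1, 38, 79.6 and 75.5 CPM and csa libraries 184, 244, 175 and 106 CPM. The group means were 102 ± 16.8 in WT SD, 120 ± 22.1 in csa SD, 66.8 ± 19.4 in WT LD and 177 ± 56.9 in csa LD (CPM ± SD, n = 4). CSA did not differ between genotypes in SD (log2 fold change 0.22, edgeR adjusted p = 0.417) and was higher in csa in LD (log2 fold change 1.40 ± 0.22 SE, edgeR adjusted p = 0.000963). The mutant therefore still made the transcript, and its level could not check the genotype labels; the kind of mutation is not given in the sources used here. In leaves CSA was rare, with means of 1.16 ± 1.36 CPM in WT SD, 0.727 ± 0.887 in csa SD, 0.37 ± 0.382 in WT LD and 0.223 ± 0.206 in csa LD (SD, n = 12). The leaf values were highest at night, at 2.48 and 4.13 CPM in the 2 libraries of WT SD at 00:00.

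Genotype labels of the leaves were therefore read from 8 marker genes that differed between csa and WT by a log2 difference of at least 2. They were chosen from measured values of anthers and of LD leaves outside the collections at 12:00. Most of them lie in the first 8000 locus numbers of chromosome 1, and the rest on chromosome 3. Markers that lie close together may be inherited together, so the 8 are not independent checks of a library. In 20 SD leaf libraries outside 12:00, not used in that choice, 3 of 160 marker values lay nearer the other genotype. In the 4 libraries labelled SD 12:00, 31 of 32 marker values lay nearer the genotype opposite to the label, in WT and in csa. In the 4 LD libraries at 12:00 it was 0 of 32. The gene counts, list tests and diel calls of leaves were therefore also computed without the libraries labelled 12:00.

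**Figure D1:**
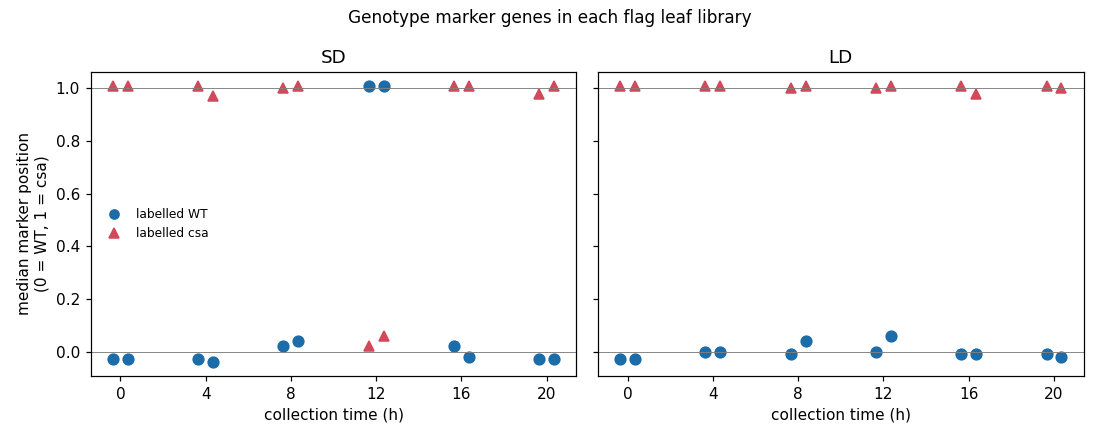
Median position of 8 genotype markers in each leaf library (y axis, 0 for the WT mean and 1 for the csa mean, no unit) against collection time in h, in SD and in LD; each point is a library. The 4 libraries labelled SD 12:00 sit at the position of the genotype opposite to their label.

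The first comparison asked what the csa mutation changed in anthers under SD, where the mutant is sterile. Single genes of sugar import, starch synthesis and late pollen fell steeply, although the sugar and starch lists as a whole did not pass with camera. OsSWEET5 (LOC_Os05g51090), a sugar transporter, fell from 31.9 ± 9.11 CPM in WT to 0.738 ± 0.368 in csa (SD, n = 4; log2 fold change −5.43 ± 0.32 SE, edgeR adjusted p = 9.99e-07). The cell wall invertase OsCIN3 (LOC_Os04g33720), which splits sucrose outside the pollen, fell from 601 ± 256 to 18.5 ± 8.14 CPM (log2 fold change −5.02, n = 4). The granule-bound starch synthase GBSSI (LOC_Os06g04200) fell from 50 ± 30.6 to 1.15 ± 0.24 CPM and the late pollen factor MADS63 (LOC_Os06g11970) from 33.5 ± 18.2 to 0.217 ± 0.112 CPM (SD, n = 4; log2 fold changes −5.36 and −7.16). Across all genes, 6510 rose and 5457 fell at adjusted p below 0.05 in the edgeR quasi-likelihood test. Of these, 1248 rose and 2441 fell at least 2-fold.

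In SD anthers 8 of 26 genes of starch and sucrose metabolism rose and 13 fell, or 14 fell when adjusted over the list alone. UGP2 (LOC_Os02g02560), which makes UDP-glucose, fell from 151 ± 53.5 to 12.7 ± 2.93 CPM (SD, n = 4), SSIIa (LOC_Os06g12450) from 71 ± 15.2 to 14.5 ± 2.01 CPM and ISA1 (LOC_Os08g40930) from 118 ± 24 to 38.2 ± 8.26 CPM. Over both times the list as a whole did not pass with camera (camera adjusted p = 0.0724), but it passed downward with fry (fry adjusted p = 0.00589). Among 22 sugar transporters and invertases 7 rose and 8 fell, also when adjusted over the list alone. OsMST6 (LOC_Os07g37320) rose from 11.4 ± 3.93 to 47.1 ± 2.65 CPM, OsMST8 (LOC_Os01g38670) fell from 373 ± 119 to 175 ± 15.1 CPM, and the sucrose transporter OsSUT1 (LOC_Os03g07480) did not differ at 7.1 ± 2.32 and 8.2 ± 1.23 CPM (SD, n = 4; edgeR adjusted p = 0.676). OsSUT3 (LOC_Os10g26470) had 0 counts in csa and 0.83 ± 0.73 CPM in WT, where WT SD 04:00 replicate 2 also had 0. The median log2 fold change of this list was 0.13 and its mean −0.80, or −0.69 with OsSUT3 in csa at a floor of 3 counts over the group; the list test pointed down and was not significant (camera adjusted p = 0.927).

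Tapetum and pollen wall genes fell in SD, 13 of 18 with none rising, or 13 with 1 rising when adjusted over the list alone (camera adjusted p = 0.000139; adjusted p = 0.429 with an estimated correlation). The Ubisch body protein gene RAFTIN1 (LOC_Os08g38810) fell from 1690 ± 625 to 575 ± 86.1 CPM, the transporter gene ABCG26 (LOC_Os10g35180) from 510 ± 83.7 to 163 ± 15.5 CPM, and EAT1 (LOC_Os04g51070), a regulator of tapetal cell death, from 124 ± 24.4 to 45.7 ± 9.55 CPM (SD, n = 4). TIP2 (LOC_Os01g18870), an earlier tapetum regulator, fell from 22 ± 4.56 to 11.2 ± 2.36 CPM. The sporopollenin genes CYP703A3 (LOC_Os08g03682) (82.4 ± 64.9 to 12 ± 13.2 CPM), PKS1 (LOC_Os10g34360) (391 ± 322 to 83.1 ± 80.3 CPM) and ACOS12 (LOC_Os04g24530) (93.5 ± 102 to 26.9 ± 27.6 CPM) also fell, with a spread within groups near or above the mean. The falls of PKS1 and ACOS12 no longer passed without WT SD 16:00 replicate 1 (edgeR adjusted p = 0.142 and 0.427), WT SD 04:00 replicate 1 (0.0599 and 0.19) or any of the 4 csa SD libraries (0.0588 to 0.0871 and 0.0917 to 0.13), and that of ACOS12 also without WT LD 16:00 replicate 1 or either csa LD 16:00 library (0.05 to 0.0522) or with the replicate number as a block (0.0893). Of 7 late pollen genes 5 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0297; adjusted p = 0.515 with an estimated correlation); OsSWEET5 and OsSUT1 belong to this list too. EXPB1 (LOC_Os03g01610), a pollen expansin, had 15.6, 66.4, 76.8 and 0.578 CPM in the WT libraries and 3 counts in all of csa; its fall no longer passed without WT SD 04:00 replicate 1 (edgeR adjusted p = 0.0802). All 5 photosynthesis genes rose (camera adjusted p = 0.0208; adjusted p = 0.504 with an estimated correlation), and RBCS3 (LOC_Os12g19381) went from 451 ± 298 to 962 ± 177 CPM (SD, n = 4). Of 11 jasmonate genes 2 rose and 4 fell, with JAZ9 (LOC_Os03g08310) falling from 197 ± 110 to 24.2 ± 7.41 CPM and JAR1 (LOC_Os05g50890) from 523 ± 77.5 to 206 ± 37 CPM. That list had a median of 0.10 and a mean of −0.33 on the log2 scale and a test pointing down (camera adjusted p = 0.554). Of 13 flowering and photoreceptor genes 7 rose and 2 fell (camera adjusted p = 0.226); DTH8 (LOC_Os08g07740) fell from 21 ± 5.51 to 5.56 ± 0.886 CPM and PHYA (LOC_Os03g51030) rose from 98.4 ± 34.8 to 168 ± 15.9 CPM. The 5 heat shock genes gave 2 rises (camera adjusted p = 0.644), and of CSA and its paralog the paralog CSA2 (LOC_Os05g41166) fell from 7.96 ± 0.681 to 2.19 ± 0.981 CPM (camera adjusted p = 0.386).

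Some genes without a symbol, picked by the naming rule, also stood far apart between the genotypes in anthers. LOC_Os01g67690 was at 70.5 ± 8.82 CPM in csa SD and 0.148 ± 0.297 in WT SD, and at 82.4 ± 13.3 CPM in csa LD and 0.0784 ± 0.157 in WT LD (SD, n = 4). LOC_Os06g45230 and LOC_Os06g45190 had 0 counts in csa SD, and 46.9 ± 50.2 and 38.9 ± 31.3 CPM in WT SD, with a spread near or above the mean.

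Anthers were sampled in the light and in the dark, so the SD comparison was also made at each time. At 16:00, 5653 genes rose and 4908 fell in csa, and at 04:00, 5251 rose and 5207 fell (edgeR, n = 2 per group and time). Of 13 clock genes 10 rose and 0 fell at 16:00 (camera adjusted p = 0.000139; adjusted p = 0.052 with an estimated correlation) and 2 rose and 4 fell at 04:00 (camera adjusted p = 0.106); differences between the 2 times were not tested. The morning clock gene OsLHY (LOC_Os08g06110) was at 44.5 ± 2.64 CPM in WT and 106 ± 2.79 in csa at 16:00, and at 469 ± 59.6 and 540 ± 34.6 CPM at 04:00 (SD, n = 2). OsPRR73 (LOC_Os03g17570) went the other way between times, from 305 ± 16.1 CPM in WT to 475 ± 25.9 in csa at 16:00 and from 56.1 ± 3.27 to 17.1 ± 0.819 CPM at 04:00. Over both times the clock list had 5 rises and 3 falls (camera adjusted p = 0.424). Photosynthesis genes rose at 04:00, 5 of 5 (camera adjusted p = 0.00341; adjusted p = 0.429 with an estimated correlation), and 0 of 5 changed at 16:00 (camera adjusted p = 0.554). Heat shock genes gave 3 rises at 04:00 (camera adjusted p = 0.0324; adjusted p = 0.502 with an estimated correlation) and 3 falls at 16:00 (camera adjusted p = 0.0941). Jasmonate genes fell at 16:00, 5 of 11 (camera adjusted p = 0.0175; adjusted p = 0.237 with an estimated correlation), and at 04:00 4 rose and 2 fell (camera adjusted p = 0.412). Starch and sucrose genes gave 4 rises and 13 falls of 26 at 04:00 (camera adjusted p = 0.0361; adjusted p = 0.515 with an estimated correlation) and 7 rises and 8 falls at 16:00 (camera adjusted p = 0.446). Tapetum genes gave 1 rise and 8 falls of 18 at 16:00 (camera adjusted p = 0.00341; adjusted p = 0.515 with an estimated correlation) and 0 and 11 at 04:00 (camera adjusted p = 0.00284; adjusted p = 0.514 with an estimated correlation). Late pollen genes gave 5 falls of 7 at each time (camera adjusted p = 0.0453 at 16:00, with 0.515 at an estimated correlation, and 0.106 at 04:00). Without WT SD 16:00 replicate 2 the count at 16:00 was 6796, and without csa SD 04:00 replicate 1 the count at 04:00 was 5701.

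**Figure D2:**
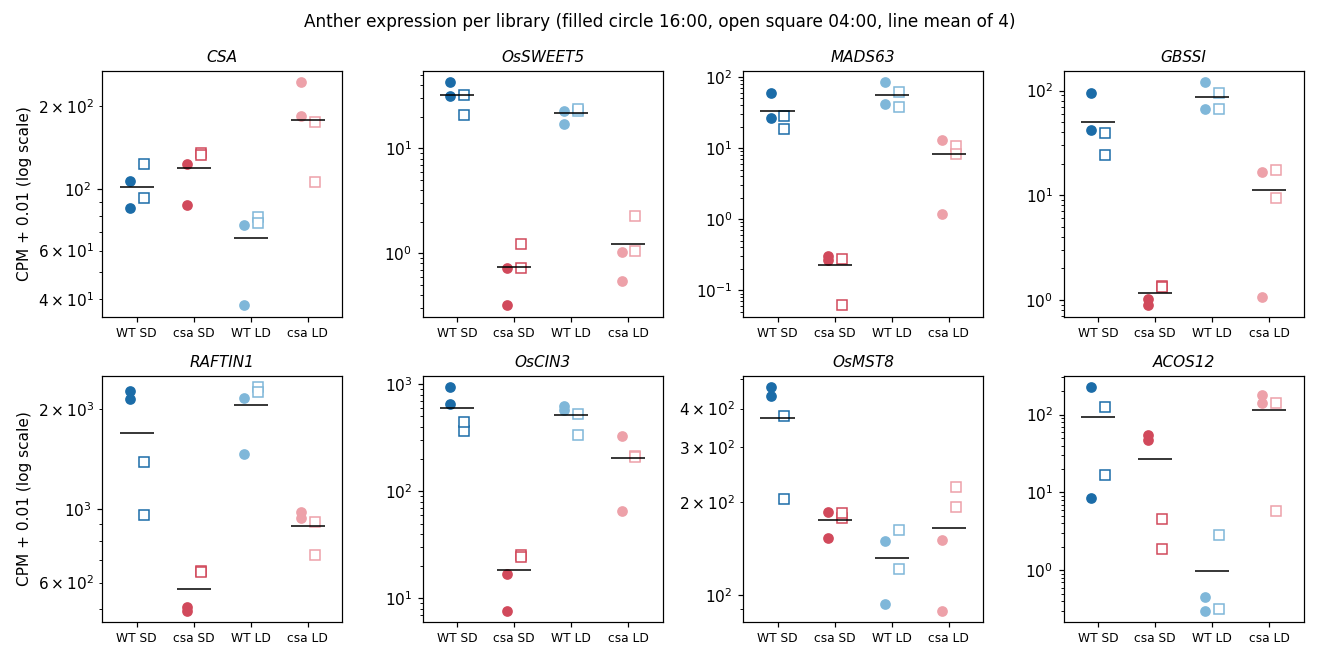
CPM plus a small offset on a log scale (y axis) of 8 genes in 16 anther libraries by genotype and photoperiod (x axis); filled circles are 16:00, open squares 04:00 and lines the mean of 4 libraries. OsSWEET5, MADS63 and GBSSI are lower in csa in both photoperiods, OsCIN3 is lowest in csa SD, and ACOS12 is lowest in WT LD.

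The same comparison in LD anthers asked what the mutation changes where csa is fertile. OsSWEET5, GBSSI, UGP2 and OsCIN3 fell in LD as well, OsCIN3 by less than in SD. OsSWEET5 fell from 21.6 ± 3.07 to 1.22 ± 0.745 CPM (SD, n = 4; log2 fold change −4.23 ± 0.30 SE, edgeR adjusted p = 6.53e-06), GBSSI from 87.3 ± 25.9 to 11.1 ± 7.59 CPM and UGP2 from 305 ± 127 to 44.9 ± 29.1 CPM. OsCIN3 fell from 517 ± 127 to 204 ± 107 CPM (log2 fold change −1.32, edgeR adjusted p = 0.0202). Of 5 sporopollenin genes 4 went up in csa from low levels in WT. ACOS12 rose from 0.967 ± 1.23 to 116 ± 75.6 CPM (log2 fold change 7.12 ± 1.38 SE, edgeR adjusted p = 0.00249), CYP704B2 (LOC_Os03g07250) from 3.54 ± 4.97 to 201 ± 119 CPM, ABCG15 (LOC_Os06g40550) from 0.554 ± 0.489 to 26.2 ± 16.5 CPM and PKS1 from 9.52 ± 11 to 231 ± 139 CPM (SD, n = 4). These 4 genes were far lower in csa LD 04:00 replicate 2 than in replicate 1. ACOS12 was at 5.75 and 141 CPM, CYP704B2 at 22.3 and 253, ABCG15 at 1.76 and 32.7, and PKS1 at 22.4 and 314. For PKS1 that overlapped with WT LD 04:00 replicate 2 at 25.5 CPM. In all, 4722 genes rose and 4155 fell (edgeR), of which 1806 and 1864 moved at least 2-fold.

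Starch and sucrose genes fell in LD, 17 of 26 against 3 rises, or 17 against 4 when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.276 with an estimated correlation). BEIIb (LOC_Os02g32660) fell from 238 ± 68.3 to 58 ± 13.4 CPM, SSIIa from 76.9 ± 8.96 to 22.3 ± 4.53 CPM and HXK5 (LOC_Os05g44760) from 345 ± 87.6 to 134 ± 27.9 CPM, while sucrose synthase SUS1 (LOC_Os03g28330) rose from 849 ± 264 to 2080 ± 745 CPM (SD, n = 4). All 7 late pollen genes fell (camera adjusted p = 0.000346; adjusted p = 0.429 with an estimated correlation). Among them MADS63 fell from 56.4 ± 21.9 to 8.21 ± 5.08 CPM and RUPO (LOC_Os06g03610), a kinase gene of the pollen tube, from 70.3 ± 49.1 to 5.93 ± 8.57 CPM. Of 22 sugar transport genes 5 rose and 8 fell, or 6 and 9 when adjusted over the list alone, with a median of 0 and a mean of −0.75 (camera adjusted p = 0.446). OsMST7 (LOC_Os01g38680) rose from 7.03 ± 3.77 to 58.3 ± 28.1 CPM, and OsMST8 did not differ at 132 ± 30.5 and 164 ± 58.6 CPM (edgeR adjusted p = 0.371). The tapetum list split into 4 rises and 7 falls of 18, or 6 and 7 when adjusted over the list alone. Its median of 0.20 and mean of 1.40 were positive while its test pointed down (camera adjusted p = 0.106). RAFTIN1 fell from 2050 ± 398 to 890 ± 111 CPM, ABCG26 from 634 ± 73.1 to 279 ± 58.5 CPM and GAMYB (LOC_Os01g59660) from 313 ± 10.3 to 200 ± 34.8 CPM (SD, n = 4).

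None of the remaining lists passed with camera in LD. With fry the clock (fry adjusted p = 0.00415) and jasmonate lists (0.00141) passed downward, and CSA with its paralog (0.0336) upward. Clock genes gave 1 rise and 3 falls of 13 (camera adjusted p = 0.171), flowering genes 3 rises and 4 falls of 13 (median 0.22, mean 0.02, test down, camera adjusted p = 0.912), and jasmonate genes 1 rise and 2 falls of 11 (camera adjusted p = 0.16). JAR1 fell from 787 ± 41.5 to 249 ± 58.3 CPM and DTH8 from 23.9 ± 2.42 to 8.54 ± 1.51 CPM (SD, n = 4). Of 5 photosynthesis genes 2 rose (camera adjusted p = 0.493), of 5 heat shock genes 1 fell (camera adjusted p = 0.912), and of CSA and its paralog CSA rose (camera adjusted p = 0.446). LOC_Os11g43230 had 19.2 CPM in csa LD and 0 counts in WT LD, at least 523-fold more against the floor of 3 counts. LOC_Os01g06510 had 0 counts in csa LD and 6.19 CPM in WT LD, at least 182-fold less. Both stood apart the same way in SD anthers. LOC_Os11g43230 was at 14.3 ± 2.77 CPM in csa SD and 0.0657 ± 0.103 in WT SD. LOC_Os01g06510, which is among the genotype markers of the leaves, was at 0.0257 ± 0.0297 and 8.97 ± 2.01 CPM (SD, n = 4).

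Whether the mutation acted differently in SD and LD was tested by the genotype by photoperiod interaction in anthers, taken as the csa to WT difference in SD minus that in LD. It was significant for 4489 genes, 2054 with a positive and 2435 with a negative value (edgeR). OsCIN3 lost far more in SD than in LD (interaction −3.70 on the log2 scale). OsMST8 fell in SD only (interaction −1.32), and OsMST7 rose in LD and had 58.2 ± 18.9 CPM in WT SD and 32.1 ± 16.3 in csa SD (SD, n = 4; interaction −4.04). Of 5 sporopollenin genes 3 fell in SD and rose in LD, with interactions of −9.95 for ACOS12, −7.76 for PKS1 and −8.47 for ABCG15; the falls of ACOS12 and PKS1 in SD no longer passed without WT SD 16:00 replicate 1 (edgeR adjusted p = 0.427 and 0.142) or several other libraries, nor that of ACOS12 with the replicate number as a block (0.0893). ABCG15 overlapped between genotypes in SD, at 47.1, 4.12, 28.6 and 8.15 CPM in WT and 8.35, 12.5, 1.66 and 1.38 CPM in csa. Its fall in SD was not followed over the fits without a library. CYP704B2 rose in LD but did not pass in SD, at 147 ± 152 CPM in WT and 53.7 ± 44.6 in csa (edgeR adjusted p = 0.109; interaction −8.08). CYP703A3 fell in SD but did not pass in LD, at 19 ± 2.5 CPM in WT and 51.5 ± 40.7 in csa (edgeR adjusted p = 0.209). Of 18 tapetum genes 8 had a negative and 1 a positive interaction, or 13 and 1 when adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.515 with an estimated correlation). Clock genes went toward a positive interaction, 4 against 1 of 13, or 6 against 1 when adjusted over the list alone (camera adjusted p = 0.0208; adjusted p = 0.237 with an estimated correlation), with OsLHY at 1.12. Photosynthesis genes did so too, 2 of 5, or 3 when adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.515 with an estimated correlation). CSA and CSA2 both had negative values (camera adjusted p = 0.0315; adjusted p = 0.325 with an estimated correlation).

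The interaction of the starch list was not significant, with 4 positive and 2 negative genes of 26 (camera adjusted p = 0.106), nor was that of late pollen genes, with 1 of each sign among 7 (camera adjusted p = 0.82). Sugar transport genes had 3 of each sign among 22, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.446). Flowering genes had 3 positive of 13 (camera adjusted p = 0.176), jasmonate genes 3 positive and 1 negative of 11 (median −0.03, test up, camera adjusted p = 0.493), and heat shock genes 1 positive of 5 (camera adjusted p = 0.446). The interaction count fell over 1.5 times without any 1 of 6 libraries, to between 2157 and 2968 genes.

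Anthers in SD and in LD were compared within each genotype. Whether groups differed in anther stage was examined for the sporopollenin genes only, so stage was not told apart from day length or genotype. In WT anthers the sporopollenin genes ACOS12 and PKS1 and the monosaccharide transporter genes OsMST7 and OsMST8 were higher in SD, while most changed sugar transport genes and the late pollen gene RUPO were lower. ACOS12 was at 93.5 ± 102 CPM in SD and 0.967 ± 1.23 in LD (SD, n = 4; log2 fold change 6.87 ± 1.37 SE, edgeR adjusted p = 0.00425), and PKS1 at 391 ± 322 and 9.52 ± 11 CPM. OsMST7 was at 58.2 ± 18.9 and 7.03 ± 3.77 CPM and OsMST8 at 373 ± 119 and 132 ± 30.5 CPM. RUPO was at 1.47 ± 1.21 CPM in SD and 70.3 ± 49.1 in LD, and OsSUT1 at 7.1 ± 2.32 and 31.4 ± 16.1 CPM. In WT, 3602 genes were higher and 3675 lower in SD (edgeR), and in csa 1825 were higher and 2088 lower. CSA was at the threshold in WT (log2 fold change 0.63, edgeR adjusted p = 0.0515). It passed with DESeq2 (adjusted p = 0.0141), without a filter (1.85e-06), and without WT SD 04:00 replicate 1 (0.0473), WT LD 16:00 replicate 1 (0.00859) or csa LD 04:00 replicate 1 or 2 (0.0386 and 0.0408).

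In WT anthers the clock genes OsPRR37 (LOC_Os07g49460) (94.7 ± 50.1 CPM in SD, 56.3 ± 48.9 in LD; SD, n = 4) and 4 others were higher in SD and 2 of 13 lower, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.106). In csa 8 of 13 were higher and 0 lower, or 10 and 1 when adjusted over the list alone (camera adjusted p = 1.88e-06; adjusted p = 0.0257 with an estimated correlation), with OsLHY at a log2 fold change of 1.52 over both times; it was higher in SD at 16:00 (104 and 108 against 10.6 and 11.2 CPM) but not at 04:00 (516 and 565 against 549 and 740 CPM). Jasmonate genes were lower in SD in WT, 6 of 11 (camera adjusted p = 0.014; adjusted p = 0.237 with an estimated correlation), and in csa, 3 of 11 (camera adjusted p = 0.0247; adjusted p = 0.246 with an estimated correlation). Heat shock genes were lower in WT, 3 of 5 (camera adjusted p = 0.0175; adjusted p = 0.429 with an estimated correlation), with HSP17.4 (LOC_Os03g16020) at 3.52 ± 0.794 CPM in SD and 10.2 ± 1.51 in LD (SD, n = 4); in csa 2 were lower, with the same camera and estimated values. Starch genes were lower in WT, 8 against 2 of 26 (camera adjusted p = 0.0231; adjusted p = 0.514 with an estimated correlation), and gave 2 higher and 5 lower in csa (camera adjusted p = 0.912). Tapetum genes gave 5 higher and 2 lower of 18 in WT, or 7 and 5 when adjusted over the list alone (camera adjusted p = 0.981). In csa 8 were lower and 1 higher, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.000197; adjusted p = 0.431 with an estimated correlation).

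Sugar transport genes gave 3 higher and 8 lower of 22 in WT (camera adjusted p = 0.106) and 2 and 2 in csa (camera adjusted p = 0.493). Late pollen genes gave 2 lower of 7 in WT (camera adjusted p = 0.0537) and 3 lower in csa (camera adjusted p = 0.174). Flowering genes gave 1 higher and 3 lower of 13 in WT (camera adjusted p = 0.912), where PHYA was at 98.4 ± 34.8 CPM in SD and 178 ± 50 in LD (SD, n = 4), and 5 higher and 1 lower in csa (camera adjusted p = 0.0941). Photosynthesis genes gave 1 lower of 5 in WT (camera adjusted p = 0.384) and 1 higher in csa, or 3 when adjusted over the list alone (camera adjusted p = 0.0453; adjusted p = 0.515 with an estimated correlation). CSA2 was higher in SD in WT, at 7.96 ± 0.681 and 4.75 ± 0.529 CPM (list of both, camera adjusted p = 0.106), and lower in csa (camera adjusted p = 0.0983). The call of CSA2 in WT was lost without any one of 7 of the 8 WT libraries, all but WT SD 04:00 replicate 1 (edgeR adjusted p = 0.0536 to 0.0797). LOC_Os06g47110 had 2 counts in all of WT SD and 14.5 ± 11.9 CPM in WT LD (SD, n = 4). Without WT SD 16:00 replicate 1 the WT count was 4128, and without csa LD 04:00 replicate 1 the csa count was 1241.

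In flag leaves the genotypes differed little in SD. Only 48 genes rose and 61 fell in csa (edgeR), with 14 and 25 of them at least 2-fold, and 1955 genes had an unadjusted p below 0.05. No member of any list passed the threshold. LOC_Os06g03520 fell from 55.7 ± 82 to 38.2 ± 59.5 CPM (SD over 6 times, n = 12; log2 fold change −0.75 ± 0.12 SE, edgeR adjusted p = 0.000294). Log2 fold changes of leaves are averages over the times, so that they can differ from the ratio of the mean CPM. The starch list was shifted up (camera adjusted p = 0.0189; adjusted p = 0.523 with an estimated correlation). Without the libraries labelled 12:00, whose markers matched the other genotype, 271 genes differed (118 up, 153 down), of which 100 were shared with the 109. DESeq2 called 194 genes, 109 of them shared.

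In LD leaves, csa had more transcript of the photosynthesis genes. RBCS3, a Rubisco small subunit gene, rose from 17800 ± 4850 to 27600 ± 9630 CPM (SD over 6 times, n = 12; log2 fold change 0.59 ± 0.10 SE, edgeR adjusted p = 0.000552). RBCS2 (LOC_Os12g17600) rose from 13200 ± 7100 to 21200 ± 12600 CPM, CAB2R (LOC_Os01g41710) from 715 ± 902 to 1230 ± 1300 CPM and RCA (LOC_Os11g47970) from 26000 ± 27700 to 37500 ± 38400 CPM. Of 5 photosynthesis genes 4 rose (camera adjusted p = 1e-08; adjusted p = 0.015 with an estimated correlation). The ADP-glucose pyrophosphorylase genes AGPL1 (LOC_Os05g50380) and AGPS1 (LOC_Os09g12660) fell, from 15.7 ± 20.2 to 5.4 ± 3.11 CPM and from 24.1 ± 19 to 12 ± 6.12 CPM, and were the only 2 of 23 starch genes to pass, or 2 with 4 rises when adjusted over the list alone (camera adjusted p = 0.989). The clock list gave 1 fall of 13, OsPRR59 (LOC_Os11g05930) from 57.2 ± 38.8 to 50.4 ± 35.1 CPM (camera adjusted p = 0.989), and the other lists 0. In total 395 genes rose and 361 fell (edgeR), with 42 and 119 at least 2-fold. Without the libraries labelled 12:00, 326 genes differed, and the falls of AGPL1 (edgeR adjusted p = 0.0649), AGPS1 (0.365) and OsPRR59 (0.169) no longer passed.

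Several leaf genes without a symbol were nearly confined to one genotype in LD. LOC_Os01g05510 was at 15.2 ± 1.94 CPM in csa LD and 0.00413 ± 0.0143 in WT LD, and LOC_Os01g05530 at 12 ± 4.26 and 0.0466 ± 0.067 CPM (SD, n = 12). LOC_Os01g05289 was at 0.0252 ± 0.0467 CPM in csa LD and 7.52 ± 2.02 in WT LD, and LOC_Os01g03180 at 0.0118 ± 0.0277 and 5.87 ± 4.45 CPM. In SD, with the libraries labelled 12:00 under their labels, they were less so: LOC_Os01g05510 was at 2.95 ± 6.84 CPM and LOC_Os01g05530 at 2.77 ± 6.48 in WT, and LOC_Os01g05289 at 0.728 ± 1.55 CPM and LOC_Os01g03180 at 0.276 ± 0.563 in csa (SD, n = 12). All 4 lie in the first 8000 locus numbers of chromosome 1, as did 55 of the 161 genes with at least a 2-fold difference in LD.

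The genotype by photoperiod interaction in leaves was significant for 65 genes, 24 positive and 41 negative (edgeR); 2402 had an unadjusted p below 0.05. Photosynthesis genes were shifted down as a list (camera adjusted p = 1.42e-05, or 0.0716 with an estimated correlation). All 5 interactions were negative, from −0.326 for RCA to −0.593 for CAB2R. RBCS3 was at 29000 ± 6960 CPM in WT SD and 29900 ± 5210 in csa SD (SD, n = 12). None of the 5 passed by itself, or 4 when adjusted over the list alone. AGPL1 was the only list gene to pass (interaction 1.46 ± 0.31 SE, edgeR adjusted p = 0.0262), and it no longer passed without the libraries labelled 12:00 (edgeR adjusted p = 0.107). LOC_Os06g15730 was at 39 ± 18.3 and 41.8 ± 24.5 CPM in WT and csa in SD and at 36.8 ± 25.9 and 15.4 ± 10.9 CPM in LD (SD, n = 12; interaction 1.47). Without the libraries labelled 12:00 the count was 29, of which 17 were shared, and DESeq2 called 244.

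Far more leaf genes differed between SD and LD than between the genotypes. Only SD plots were covered, so that day length could not be told apart from the cover or the plot. In WT 5338 genes were higher and 4809 lower in SD (edgeR), and in csa 5119 and 4405. Starch genes of the WT leaf were mostly lower in SD, 14 of 23 against 4 higher, or 14 against 5 when adjusted over the list alone. Starch synthase SSI (LOC_Os06g06560) was at 61.7 ± 88.7 CPM in SD and 92 ± 80.8 in LD (SD over 6 times, n = 12; log2 fold change −1.55 ± 0.14 SE, edgeR adjusted p = 2.52e-10) and AGPS1 at 6.19 ± 2.94 and 24.1 ± 19 CPM. The starch list test gave a camera adjusted p of 0.0632, and of 0.7 with an estimated correlation. Without the libraries labelled 12:00 the camera adjusted p was 0.0323 at the preset correlation, and no value with an estimated correlation is given for that fit. RBCS3 was higher in SD, at 29000 ± 6960 and 17800 ± 4850 CPM, with all 5 photosynthesis genes (camera adjusted p = 0.0311; adjusted p = 0.523 with an estimated correlation); in csa 0 of 5 differed (camera adjusted p = 0.989). Of 16 flowering genes 8 were higher and 2 lower in WT (camera adjusted p = 0.0718) and 9 and 2 in csa (camera adjusted p = 0.182). OsCOL4 (LOC_Os02g39710), a flowering repressor, was at 73.3 ± 89.4 CPM in SD and 30.5 ± 50.8 in LD, and the flowering activator Ehd1 (LOC_Os10g32600) was at 4.94 ± 5.74 and 9.62 ± 9.64 CPM (SD, n = 12). The flowering activator Hd3a (LOC_Os06g06320) differed little in mean level (log2 fold change 0.29, edgeR adjusted p = 0.0228), and the call was lost without any one of WT SD 20:00 replicate 2, WT LD 12:00 or 16:00 replicate 1, or WT LD 20:00, 00:00 or 04:00 replicate 2 (0.0504 to 0.0803). Without the libraries labelled 12:00, 9433 genes differed in WT and 8979 in csa.

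Clock genes gave 7 higher and 1 lower of 13 in WT leaves (camera adjusted p = 0.182) and 6 and 1 in csa, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.182). Jasmonate genes were higher in SD in csa, 8 of 11 (camera adjusted p = 0.0311; adjusted p = 0.751 with an estimated correlation), and 4 of 11 in WT (camera adjusted p = 0.268), where JAZ8 (LOC_Os09g26780) was at 7.16 ± 4.05 CPM in SD and 3.66 ± 2.67 in LD (SD, n = 12). Heat shock genes gave 2 lower of 4 in each genotype (camera adjusted p = 0.369 in both). HSP18.0 (LOC_Os01g08860) was at 2.57 ± 3.98 and 22.6 ± 45.7 CPM in WT (edgeR adjusted p = 6.32e-05), and its adjusted p was 0.0589 without the libraries labelled 12:00; WT LD 12:00 replicate 2 stood apart in heat shock genes. Sugar transport genes gave 3 higher and 4 lower of 14 in WT (camera adjusted p = 0.734) and 2 and 6 in csa (camera adjusted p = 0.696). Starch genes in csa gave 2 higher and 9 lower of 23 (camera adjusted p = 0.249). Pollen lists had few expressed members in leaves, with 2 of 7 tapetum genes and 1 of 2 late pollen genes higher in WT (camera adjusted p = 0.989 for both). LOC_Os06g47930 was at 12.6 ± 6.46 CPM in WT SD and 0.774 ± 0.298 in WT LD (log2 fold change 3.87).

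The leaf time course asked how the daily rhythm depends on day length and on CSA. Peak times are clock hours, not hours after first light. All 13 clock genes followed a 24 h rhythm in all 4 groups. The morning gene OsLHY peaked at 7.8 h in WT SD and at 6.2 h in WT LD (diel pattern, edgeR adjusted p = 9.42e-11), and at 7.7 and 6.2 h in csa (edgeR adjusted p = 2.27e-10). It reached 7690 ± 910 CPM at 08:00 in WT SD and 5900 ± 52.6 in WT LD (SD, n = 2). Hd3a peaked at 9.6 h in SD and 7.6 h in LD in WT (edgeR adjusted p = 0.0169) and at 10.1 and 7.4 h in csa (edgeR adjusted p = 0.00359). OsMADS51 (LOC_Os01g69850), a flowering activator, was rhythmic in SD in WT and csa and not in LD (edgeR adjusted p = 0.417 and 0.381), and its pattern differed between day lengths (edgeR adjusted p = 0.000211 in WT and 0.00128 in csa). With collection time as a factor in place of the cosine it was rhythmic in csa LD too (edgeR adjusted p = 0.011). OsZTL2 (LOC_Os02g05700) peaked at 8.1 h in SD and 4.6 h in LD in WT (edgeR adjusted p = 0.0176), or 0.0925 without the libraries labelled 12:00. With collection time as a factor in place of the cosine, the patterns of OsPRR1 (LOC_Os02g40510), OsPRR37, OsPRR59, OsPRR73, OsPRR95 (LOC_Os09g36220), OsGI (LOC_Os01g08700), OsELF3-2 (LOC_Os01g38530) and OsLUX (LOC_Os01g74020) also differed between SD and LD, with edgeR adjusted p from 3.79e-09 to 0.0154 in WT and from 4.91e-08 to 0.0203 in csa.

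Across all leaf genes, 14954 (67.7%) were rhythmic in WT SD, 15749 (71.3%) in WT LD, 15525 (70.3%) in csa SD and 14699 (66.5%) in csa LD at edgeR adjusted p below 0.05. Of 16 flowering genes 12, 14, 13 and 13 were rhythmic in these groups. The pattern differed between SD and LD for 3086 genes (14%) in WT and 1548 (7.01%) in csa, and for 1653 and 1119 without the libraries labelled 12:00. With collection time as a factor in place of the cosine it differed for 11734 and 10901 genes, and without a filter for 4685 and 3488. Genes rhythmic in both day lengths peaked later by the clock in SD, by a median of 1.4 h in WT (quartiles 0.4 and 2.4 h, 12436 genes) and 1.4 h in csa (quartiles 0.5 and 2.3 h, 12384 genes). SD plots were covered until 6:00, and the time of dawn in LD is not given. Later peaks were therefore not told apart from a later start of light in SD. Between csa and WT the median peak shift was −0.1 h in both day lengths. The pattern differed between csa and WT for 23 genes in SD and 1 in LD (edgeR; 553 and 622 genes had an unadjusted p below 0.05), and for no gene of the clock and flowering lists. These counts depended on the model, with 243 and 527 genes with collection time as a factor and 303 and 379 without a filter. Without the libraries labelled 12:00 it differed for 0 genes in SD and 1 in LD, and without WT LD 08:00 replicate 2 for 22 in LD.

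**Figure D3:**
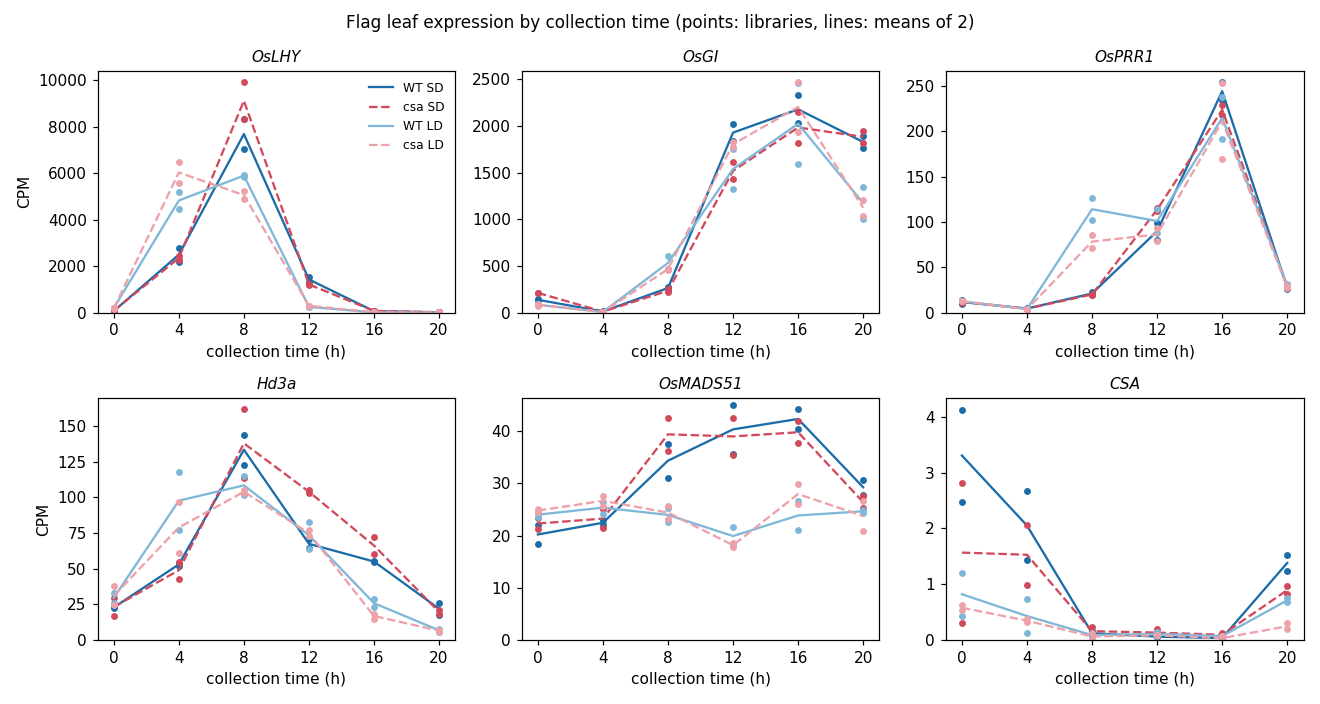
CPM (y axis) of OsLHY, OsGI, OsPRR1, Hd3a, OsMADS51 and CSA against collection time in h (x axis) in flag leaves in SD and LD; points are libraries, lines means of 2, solid for WT and dashed for csa. OsLHY peaks in the morning in all groups, and CSA is above its daytime level at night in SD.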

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

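The tests of the labels of the leaf libraries at SD 12:00, of the genes on chromosome 1 and of the sporopollenin genes were chosen after the result was seen, except that of replicates taken at different anther stages; the other splits of the libraries were planned. The tests of a linked segment on chromosome 1 and of younger csa anthers in SD replaced earlier ones after the results of those were seen: the earlier ones took the segment as explained by its share of the calls, and younger anthers as argued against because 4 of 5 regulators, with EAT1 among them, fell without overlap. Every value in the next paragraph stands here because the difference between csa and WT itself differed between SD and LD by an interaction test.

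In anthers 4489 genes had such a difference (edgeR), and in leaves 65. As lists, the clock (camera adjusted p = 0.0208), CSA with its paralog (0.0315), the tapetum and pollen wall (0.0112) and photosynthesis (0.033) differed in anthers, and photosynthesis in leaves (1.42e-05). None of these 5 list calls held with an estimated correlation (adjusted p = 0.237, 0.325, 0.515 and 0.515 in anthers and 0.0716 in leaves). On the log2 scale, positive anther interactions were 1.12 for OsLHY, 0.69 for OsELF3-2, 1.36 for PHYA, 1.81 for OsSWEET14 (LOC_Os11g31190), 0.74 for HXK6 (LOC_Os01g53930), 0.96 for MADS3 (LOC_Os01g10504), 1.44 for RBCS3 and 0.67 for AOS1 (LOC_Os03g55800). Negative ones were −0.74 for OsPRR37, −1.65 for CSA2, −1.17 for CSA, −3.70 for OsCIN3, −4.04 for OsMST7, −1.32 for OsMST8 and −4.37 for MADS63. The sporopollenin genes gave −8.47 for ABCG15, −9.95 for ACOS12, −8.08 for CYP704B2 and −7.76 for PKS1. Genes without a symbol gave 5.58 for LOC_Os12g36830, 4.25 for LOC_Os03g46070, −15.53 for LOC_Os02g01980 and −15.13 for LOC_Os01g03670. LOC_Os02g01980 had 3 counts in all of WT LD, so that its fitted value depends on the prior count. The calls of LOC_Os02g01980 and LOC_Os01g03670 were lost without WT SD 16:00 replicate 1 (edgeR adjusted p = 1 and 0.26), WT SD 04:00 replicate 1 (0.0764 and 0.171) or csa LD 04:00 replicate 1 (0.419 and 0.173), and that of LOC_Os02g01980 also without csa SD 04:00 replicate 1 or WT LD 04:00 replicate 1 (0.0509 and 0.0525). The call of CSA was lost without WT SD 16:00 replicate 1, WT SD 04:00 replicate 2, csa SD 16:00 replicate 1, either csa SD 04:00 library, WT LD 04:00 replicate 1 or csa LD 04:00 replicate 1 (edgeR adjusted p = 0.0527 to 0.0651).

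In most comparisons no other split of the same libraries gave as many genes as the real one. A true difference stays in the residual spread of the other splits and lowers their counts. The splits also do not tell genotype or day length from factors that go with them, such as anther stage. In anthers only the real split, 1 of 34, gave as many genes for csa against WT in SD (5777, highest other 80) and in LD (7244, highest other 1). The same held for SD against LD in WT (1904, highest other 316) and in csa (2123, highest other 1), and for 1 of 100 splits of the interaction (1305, highest other 352). In leaves it was 1 of 100 for csa against WT in LD (211, highest other 2), and for SD against LD in WT (6246, highest other 7) and in csa (6295, highest other 4). It was also 1 of 100 for the diel pattern of SD against LD in WT (2288, highest other 91) and in csa (1268, highest other 38). It was 1 of 100 as well for csa against WT in SD leaves, but with 5 genes against a highest other of 3 and with the libraries labelled SD 12:00, whose markers matched the other genotype, kept under their labels; no splits without them were run in any leaf comparison. For the diel pattern of csa against WT in SD chance could not be excluded, since 9 of 100 splits gave at least the real 3 genes (highest other 4748). For the leaf interaction (highest other 10) and the diel pattern of csa against WT in LD (highest other 1929) the real split gave 0 genes in this fit. All 100 of 100 splits had to reach that, so they decide nothing about the genes that the contrasts called. Counts of 4748 and 1929 are no evidence of another structure of the samples. The splits of diel patterns modelled time only as a cosine and a sine and were not balanced over times. A daily pattern of another shape can then pass as a difference between the groups of a split. For the same reason the 9 of 100 decide little.

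Markers of the genotype were out of place in the leaf libraries labelled SD 12:00. An effect of midday in both photoperiods, the biological explanation tested, is argued against, since 0 of 32 marker values lay nearer the other genotype at LD 12:00. A mixture of both genotypes is argued against too, since the median marker position of each of the 4 libraries was within 0.06 of that of a pure genotype. In these 4 libraries 31 of 32 values lay nearer the other genotype. Most of the markers lie close together on chromosome 1, so the 32 values are not independent. Median positions (0 for WT, 1 for csa) were 1.01 and 1.01 in those labelled WT and 0.02 and 0.06 in those labelled csa. A midday effect in SD that moves both genotypes the same way is argued against, since the genotypes moved in opposite ways. An exchange of the labels may be the source. A midday effect in SD with opposite directions in WT and csa was not tested.

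Leaf differences between csa and WT clustered on chromosome 1. In LD 34.2% of the genes with at least a 2-fold difference (55 of 161) lay in its first 8000 locus numbers, which hold 1.67% of the tested genes, and in SD 82.1% (32 of 39). An effect of the mutation on the neighbours of CSA is argued against, since 1 such gene lay within 2000 locus numbers of CSA, where 1.16 were expected. A segment that came with the csa line and differs in sequence from WT may explain the cluster but stays open: 45% of its leaf genes tested in anthers (18 of 40) passed the same way in SD and LD anthers, more than the 10.3% of those elsewhere (9 of 87) but under the 50% asked for. In anthers the same segment held 2.30% and 2.32% of the genes with at least a 2-fold difference, against 1.52% of the tested genes, so it can explain few of those.

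Sporopollenin genes (CYP703A3, CYP704B2, ABCG15, PKS1 and ACOS12) mostly fell in SD anthers of csa and rose in LD ones, and varied within replicate pairs, by up to 16.2-fold in csa LD at 04:00 and 11.2-fold in WT SD at 16:00. Leaf tissue is argued against for the fall in SD, since RBCS3 and RBCS2 allow at most 3.78% of leaf RNA in a csa SD library, and for the rise in LD, since the highest mean of these genes in leaves was 0.889 CPM. Younger csa anthers, in which early tapetum regulators would be higher, stay open in SD: UDT1, TIP2, GAMYB and TDR (LOC_Os02g02820) all fell as averages over both times and 3 of them without overlap of the libraries at either time, but TDR (log2 fold change −0.54 ± 0.12 SE) was higher in csa at 04:00 (88.4 and 89.7 against 74 and 83 CPM). They also stay open in LD, where 4 of the 5 sporopollenin genes rose but 3 of these 4 regulators fell as averages over both times. Open too are replicates taken at different anther stages, as late pollen genes moved the opposite way in 3 of 8 pairs (exact sign-flip test, two-sided p = 0.578).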

How the results depend on the processing

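All alternatives were planned except leaves without the 12:00 collections, which were tested after the result was seen. No result that passed its threshold in either setting reversed. Direction differed between camera and fry for 3 lists that passed with neither: tapetum and pollen wall for SD against LD in WT anthers (adjusted p = 0.981 with camera and 0.857 with fry), and in leaves heat shock for csa against WT in SD and the clock for the interaction (both 0.989 and 0.999). Named genes were counted once per comparison, so that a gene can count more than once. Of 168 such pairs of a named gene and a comparison, 167 kept direction and side of the threshold with DESeq2 and 166 with RLE scaling. Without a filter 164 did. Fewer of these pairs entered 2 alternatives: with only the compared libraries 139 kept their call and 6 lost it, and without the 12:00 collections 41 kept it and 5 lost it. Of the 11967 genes of csa against WT in SD anthers DESeq2 shared 11036, and of the 756 in LD leaves 748. The cause was not tested except where fewer libraries or genes by construction give it.

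A minimum fold of 2 left, by construction, 3689 genes in anthers for csa against WT in SD, 3670 in LD, 2036 for the interaction, 2314 for SD against LD in WT, 1103 in csa, 4457 at 16:00 and 5259 at 04:00. In leaves it left 39, 161, 29, 1585 and 1329 in the order of the first 5. Without a filter leaves had 505 genes for csa against WT in SD, 1515 in LD and 642 for the interaction, and diel patterns differed for 303 (csa against WT in SD), 379 (in LD), 4685 (SD against LD in WT) and 3488 (in csa). DESeq2 gave 194 genes for csa against WT in SD leaves and 244 for the leaf interaction. With collection time as a factor, diel patterns gave 243, 527, 11734 and 10901. Without the 12:00 collections leaves gave 271 genes for csa against WT in SD, 326 in LD and 29 for the interaction, and diel patterns 0 for csa against WT in SD and 1653 for SD against LD in WT. Of the list tests 25 passed in anthers and 5 in leaves, 1 in each with an estimated correlation, and 43 and 11 with fry.

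Leaving out each library in turn gave, in anthers, 9457 to 12265 genes for csa against WT in SD, 5980 to 9121 in LD, 6796 to 10859 at 16:00, 5701 to 10721 at 04:00, 2157 to 4771 for the interaction, 4128 to 7559 for SD against LD in WT and 1241 to 4155 in csa. In leaves it gave 76 to 132 for csa against WT in SD, 515 to 1056 in LD, 32 to 147 for the interaction, 9605 to 10245 for SD against LD in WT and 8866 to 9677 in csa. Rhythmic genes numbered 13734 to 15081 in WT SD, 14832 to 15856 in WT LD, 14260 to 15624 in csa SD and 13770 to 14803 in csa LD. Diel patterns differed for 16 to 27 genes for csa against WT in SD, 0 to 22 in LD, 2127 to 3263 for SD against LD in WT and 1075 to 1720 in csa. List tests passed 20 to 27 times in anthers and 4 to 10 in leaves. Counted once per comparison and fit, named genes kept their call 4040 times, lost it 115 times and gained it 5 times. Their diel tests did so 11038, 34 and 64 times.

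Single libraries moved some counts over 1.5 times. The anther interaction was 2524 without WT SD 16:00 replicate 1, 2915 without WT SD 04:00 replicate 2, 2493 and 2968 without csa SD 04:00 replicates 1 and 2, 2293 without WT LD 04:00 replicate 1 and 2157 without csa LD 04:00 replicate 1. SD against LD in csa anthers was 1803 without csa SD 16:00 replicate 2, 1741 and 1617 without csa SD 04:00 replicates 1 and 2, 1930 without csa LD 16:00 replicate 1 and 1241 without csa LD 04:00 replicate 1. In WT it was 4128 without WT SD 16:00 replicate 1 and 4595 without WT LD 04:00 replicate 1. Without WT SD 16:00 replicate 2 the count at 16:00 was 6796, and without csa SD 04:00 replicate 1 that at 04:00 was 5701. The leaf interaction was 118 without WT LD 08:00 replicate 2, 112 without WT LD 12:00 replicate 1 and 147 without WT LD 04:00 replicate 1. It was 32 to 43 without WT SD 08:00, 16:00, 00:00 or 04:00 replicate 1, csa SD 12:00 or 04:00 replicate 2, csa SD 20:00 replicate 1, WT LD 16:00, 20:00 or 00:00 replicate 2, or csa LD 08:00 replicate 1. The leaf list tests were 10 without WT LD 12:00 replicate 1. Diel patterns of csa against WT in LD were 22 and 9 without WT LD 08:00 replicates 2 and 1, 0 without WT LD 12:00 replicate 2, and 2 to 4 without WT LD 12:00, 16:00 or 04:00 replicate 1, WT LD 00:00 replicate 2, csa LD 08:00 or 00:00 replicate 1, csa SD 08:00 replicate 1 or csa SD 04:00 replicate 2.

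With the replicate number as a block, anthers gave 11520, 8404, 3762, 6714, 3216, 10077 and 9912 genes and leaves 109, 814, 77, 10186 and 9566, none of which moved over 1.5 times. All 115 list tests kept their side, and of the named genes ACOS12 lost its fall in SD anthers (edgeR adjusted p = 0.0893). Of the diel tests of named genes 231 kept their side and 1 lost it.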

Other observations

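This part holds no tests chosen after the result was seen, but its genes and libraries were picked after their values were seen. The evening clock gene OsGI was high at 16:00 and low at 04:00 in anthers of all 4 groups. In SD it was at 762 ± 33 CPM in WT and 1500 ± 191 in csa at 16:00, and at 93.5 ± 5.37 and 31.6 ± 2.97 CPM at 04:00 (SD, n = 2). In LD it was at 1130 ± 1.92 CPM in WT and 1050 ± 27.2 in csa at 16:00, and at 33.9 ± 4.91 and 20.7 ± 2.6 CPM at 04:00; the size of the swing was not tested between groups. In SD leaves OsGI peaked at 15.7 h in WT, and in LD leaves at 14.8 h. OsPRR1 peaked at 15 h in WT SD leaves and at 13.3 h in WT LD leaves.

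Single leaf libraries stood apart from their replicate. WT LD 12:00 replicate 2 had 133 CPM of HSP17.4 where replicate 1 had 5 CPM. csa SD 16:00 replicate 1 had 387 CPM of SUS1 where replicate 2 had 15 CPM.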
